A study of Mus musculus with 2 samples.

How the data were processed

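Total RNA of mouse bone marrow leukaemic stem cells was profiled on 2 Illumina bead arrays, 1 of PirBTM MLL-AF9 cells and 1 of wild-type MLL-AF9 cells. Per the labels' protocols, RNA was extracted with Trizol, cleaned and DNase-treated on columns, checked on a Bioanalyser, and turned into biotinylated cRNA with an amplification kit made for Illumina arrays. By the array names in the labels, both arrays were positions of 1 BeadChip, so chip does not differ between the groups and array position cannot be told apart from genotype.

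The authors deposited a scanner table with, per the file headers, an average signal intensity and a detection p-value for each of 45281 probes on each array. The intensities were linear, above 0 throughout and differed in median between the arrays (161 on the PirBTM array and 148 on the wild-type array), so they were neither normalized between arrays nor background subtracted. The scanner software and its settings are not given in the sources used here. The deposited series table holds a second set of linear intensities for the same arrays. Its columns rank the probes exactly as the matching scanner columns do (Spearman's rho of 1.00 each), and the sorted values of its columns differ by at most 0.16%, which is the mark of quantile normalization. Its column medians were 148.3 and 148.2. It is uncentred and on a linear scale, and its software is not given in the sources used here.

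From the scanner table, background was corrected with limma's normexp fitted to negative controls (nec, offset 16), with the mean and SD of the negative controls inferred from the detection p-values. The inferred background was 147.2 with an SD of 14.0 on the PirBTM array and 139.3 with an SD of 11.7 on the wild-type array. The lowest signals of the arrays, 113.6 and 109.1, lay under these means. Values were quantile normalized between arrays and taken to log2. The platform annotation given with the series named 1 gene for 34885 probes and several for 18, and 10378 probes were unnamed here. Of the probes with 1 gene, 34807 were matched by gene identifier to the RefSeq table of assembly GRCm38.p6 for current symbols, and 0 symbols changed. The 34885 probes covered 19057 genes, 9172 of them with more than 1 probe. A gene was represented by its brightest probe over both arrays. No genome coordinates are printed, since the array files name no build.

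A probe counted as above background at a detection p-value below 0.01. This held for 16392 probes (36.2%) on the PirBTM array and 15137 (33.4%) on the wild-type array. Log2 ratios are PirBTM minus wild type. Where a gene was above background on 1 array only, its fold is a lower bound, "at least N-fold", set against the higher of its own dim value and the lowest value of any probe above background on the dim array. With 1 array per group there is no spread between replicates, no test of the groups and no p-value between them. In place of a replicate error, the measuring error was taken from 2944 genes with a pair of probes above background on both arrays: the log2 ratios of the brightest pair correlated across genes (Pearson r = 0.87, Spearman's rho = 0.81; genes are not independent replicates), and their difference gave an SD of 0.30 for the log2 ratio of a single probe. Of the 466 such genes whose brightest probe differed at least 2-fold, the second probe had the same sign in 96.8% and the opposite sign in 15. This error leaves out the variation between animals, sorts and RNA preparations. It also leaves out any labelling or hybridization error that both probes of a gene share, since they were read on the same arrays. The number of arrays limits the precision of every value.

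For each of 34 gene lists (699 genes, of which 627 had a named probe and the others were not analysed here), the median log2 ratio was taken over members above background on at least 1 array. Its percentile was found among 10000 random lists of the same size, matched on mean intensity in 20 bins. A list was said to stand apart under the 1st or over the 99th percentile. Among 34 lists, 0.68 would be expected outside these limits by chance if genes were independent. The percentiles describe these 2 arrays and are not p-values. Counts of members at least 2-fold higher or lower use the bound where there is one, and medians are given also with such members at their bound. The text names the 12 highest and 12 lowest ratios among genes above background on both arrays, the 4 largest bounds each way among genes with a detection p-value at or above 0.05 on the dim array, and up to 4 members of each list, the 2 highest and 2 lowest, where members with a bound were ranked by it. Other members are named as examples chosen after their values were seen. The design, the lists, the naming rule and the alternatives were fixed before the data were examined; ranking members by bound and the range that decides whether a list's median moved were set after values had been seen. The second marker sets of the closing section were picked after the first lists and top genes had been seen, and before the values of their own members were.

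The steps were tested on simulated arrays built from the real intensities and backgrounds, with 50 probes changed at each fold size. For the comparison of PirBTM with wild type, 55.3% of 47 probes changed 2-fold were called at least 2-fold, as were 98.0% of 49 changed 4-fold, 100.0% of 45 changed 8-fold and 100.0% of 35 changed 16-fold. Of 16503 unchanged probes, 0.194% were called. The simulated noise held no variation between animals, sorts or RNA preparations. Ratios of the real genes, which hold real differences too, scattered with an SD of 0.49 to 0.80 by brightness. This SD was taken from the median absolute deviation. So 0.194% is not the rate of false calls among the real genes. The list percentiles were tested apart, on ratios drawn at random and independently for each gene, with fewer random lists. Of 100 lists of 18 such genes with no shift, 4 fell outside the percentile limits. Of 100 lists shifted by 1 on the log2 scale, 99 did. Members of real lists can vary together, which this test leaves out.

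Alternatives were no background correction with 16 added, normexp without negative controls and an offset of 50, median scaling or cyclic loess in place of quantile normalization, a detection limit of 0.05 or none, the mean of all probes of a gene, the authors' deposited intensities, thresholds of 1.5-fold and 3-fold, and list members above background on both arrays only. Under these, a list's median was compared after subtracting the median of the genes it was drawn from (in the main values, the 9432 above background on at least 1 array), and was said to have moved when the change exceeded the half-width of the central 95% of random-list medians. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, were used.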

Results

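Gene expression was measured in leukaemic stem cells from mouse bone marrow. The cells carried MLL-AF9, a fusion of the histone methyltransferase gene Kmt2a (MLL) with Mllt3 (AF9) that causes acute myeloid leukaemia. The sample labelled PirBTM was compared with the sample labelled wild type. Pirb encodes an inhibitory receptor of myeloid and B cells with immunoglobulin-like domains, and what the PirBTM genotype changes in it is not given in the sources used here. Both samples were on a C57BL/6J background and labelled 9 weeks of age. Each group had 1 array with 45281 probes, so all values below are without replicates, and the 2 samples were compared, not the genotypes at large. The log2 ratio of a single probe had a measuring SD of 0.30, estimated from the disagreement between probes of the same gene on these arrays. The comparison asked how gene expression in PirBTM leukaemic stem cells differs from that in wild-type ones. No probe was named Pirb in the annotation used here, so the targeted gene is not reported and the genotype labels were not checked on the arrays.

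The PirBTM array differed from the wild-type array in many genes. Genes of antigen presentation, red cells and macrophages, such as Cd74 (219-fold), Car1 (132-fold) and C1qb (52.6-fold), were far brighter on the PirBTM array, while Hoxa9 was 25.6-fold and Meis1 19.9-fold dimmer. These folds depend on the processing: over the alternatives, log2 ratios ranged from 6.86 to 8.04 for Cd74, 5.38 to 7.28 for Car1, 5.19 to 6.00 for C1qb, -4.68 to -3.44 for Hoxa9 and -4.31 to -3.53 for Meis1. Among 7858 genes above background on both arrays, 768 (9.77%) were at least 2-fold higher and 775 (9.86%) at least 2-fold lower in PirBTM. The larger differences were mostly upward: 114 genes were at least 8-fold higher and 19 at least 8-fold lower. A further 1143 genes were above background on the PirBTM array only and 431 on the wild-type array only. With a detection p-value of at least 0.05 required on the dim array these were 836, of which 361 by at least 2-fold, against 204 and 76 the other way. The median log2 ratio of all genes above background on both arrays was -0.22, and it was 0.03 after cyclic loess and -0.10 after median scaling. Higher genes made up 49.8% of the 2-fold differences, 71.9% after cyclic loess, 62.6% after median scaling, 63.6% without background correction, 61.6% in the authors' deposited values, and 60.0% without a detection filter. The share also depended on the threshold: it was 37.3% at 1.5-fold and 69.4% at 3-fold.

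**Figure D1:**
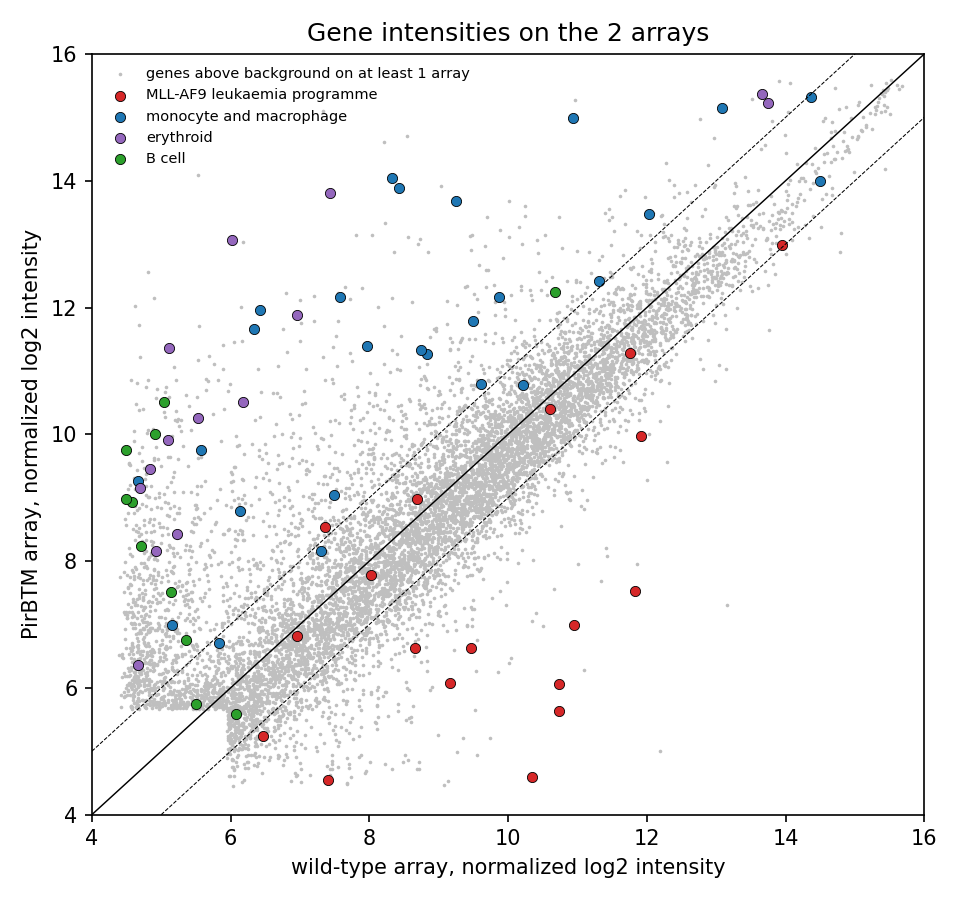
Normalized log2 intensity of each gene on the wild-type array (x axis) and the PirBTM array (y axis). Grey points are genes above background on at least 1 array, coloured points are members of 4 gene lists, the solid line marks equal intensity and the dashed lines a 2-fold difference; erythroid, B cell and monocyte genes lie mostly above the line of equal intensity (medians of 4.54, 3.53 and 2.36), and 16 of 18 genes of the MLL-AF9 programme lie below it.

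Of the 12 genes with the highest ratios, Cd74, the invariant chain of MHC class II, was 219-fold higher in PirBTM (log2 intensity 15.11 against 7.33), and a second probe gave a log2 ratio of 7.52 beside 7.77; both lay near the top of the scale on the PirBTM array (15.11 and 14.87), so this fold is uncertain. H2-Ab1, a class II chain, was 84.4-fold higher. Red cell genes were among them: Car1, a carbonic anhydrase, was 132-fold higher, Slc4a1, the band 3 anion exchanger, 83.3-fold, and Aqp1, a water channel, 58.2-fold. The complement genes C1qb and C1qc were 52.6-fold and 44.4-fold higher, and Mrc1, the macrophage mannose receptor, 46.5-fold. Cxcl12, a chemokine of marrow stroma, was 51.2-fold higher and Bgn, the matrix proteoglycan biglycan, 43.0-fold. Rgs1, a regulator of G-protein signalling, was 116-fold higher, and Retnlg, a neutrophil gene of the resistin family, 71.6-fold. On the wild-type array Rgs1 (6.18), Aqp1 (6.15) and Car1 (6.02) lay just over the lowest value above background (5.95). Their folds are therefore uncertain. Among genes with a detection p-value of at least 0.05 on the wild-type array, the largest bounds belonged to Cd72 (at least 97.4-fold), H2-Aa (at least 73.9-fold), Asb2 (at least 67.2-fold) and Fcmr (at least 54.5-fold). Cd72 is a B cell coreceptor, and Fcmr the receptor for IgM.

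Of the 12 lowest ratios, Hpgd, which breaks down prostaglandins, was 57.6-fold lower in PirBTM (log2 intensity 7.30 against 13.15). Nrg4, a neuregulin, was 28.0-fold lower, with log2 ratios of -4.80 and -4.64 for its probes. Hoxa9, Meis1 and Hoxa7, transcription factors of the MLL-AF9 programme, were 25.6-fold, 19.9-fold and 15.7-fold lower. Rab44, a Rab GTPase, was 14.9-fold lower, Prg3, an eosinophil granule protein gene, 12.6-fold, and Cdkn1c, a cyclin-dependent kinase inhibitor, 10.3-fold. Eml5 was 12.3-fold lower, Gria3 12.1-fold, Rapsn 11.9-fold and Tle6 11.5-fold. On the PirBTM array Hoxa9 (6.06), Gria3 (6.25) and Nrg4 (6.28) lay near the lowest value above background (5.67). Their folds are therefore uncertain. Among genes with a detection p-value of at least 0.05 on the PirBTM array, the largest bounds were those of Igf2bp3, an RNA-binding protein of fetal cells (at least 91.6-fold lower), Eya1 (at least 25.7-fold), Gm2629 (at least 16.8-fold) and Myadml2 (at least 14.7-fold).

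Genes of the MLL-AF9 leukaemia programme were lower in PirBTM. Of 18 members above background, 10 were at least 2-fold lower, 1 was at least 2-fold higher and 7 lay in between. The median log2 ratio was -1.99, or -1.84 with members at their bound, below all 10000 matched random lists, and 0 members were shared with another list. Hoxa5 was at least 33.5-fold lower, Eya1 at least 25.7-fold, and Myb, a transcription factor of progenitors, 4.10-fold. Bcl2, an inhibitor of apoptosis, was 2.25-fold higher (log2 ratios of 0.78 to 1.17 over its 4 probes above background), and Men1 had a log2 ratio of 0.30. Markers of other marrow cell types, given below, were higher on the same array. Stem and progenitor genes did not stand apart (percentile 35.3). Their median over 17 members was -0.27 and their mean 0.12, of opposite sign, and members went both ways. Cd34 was at least 3.98-fold lower and Prdm16 at least 3.46-fold lower, while Gfi1b and Tal1, transcription factors also used by red cell and megakaryocyte precursors, had lower bounds of 3.70 and 3.59 for their log2 ratios. Kit had a log2 ratio of -0.71.

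Genes of monocytes and macrophages were higher in PirBTM in 25 of 26 members, 21 of them at least 2-fold, with a median log2 ratio of 2.36, above all random lists. C1qb and Mrc1 were highest; Ly6c1 (log2 ratio -0.50) and Gpnmb were lowest, and the probes of Gpnmb gave 0.56 and -0.13. Late neutrophil genes had a median of 0.92, also above all random lists, with 12 of 26 members at least 2-fold higher and 2 at least 2-fold lower. Retnlg was 71.6-fold higher, and Ltf, the iron-binding granule protein lactoferrin, 19.9-fold by its brightest probe, which lay near the top of the scale on the PirBTM array (15.27) with no other probe above background on both arrays, while Olfm4 was 6.57-fold lower. Stfa1 was 2.39-fold lower by a probe near the top of the scale on the wild-type array (15.44), and its second probe gave a log2 ratio of -1.15. The probe of Retnlg also lay high, at 14.71 on the PirBTM array. Further members were bright on both arrays, such as Lcn2 (15.47 on PirBTM and 14.72 on wild type) and S100a8 (15.07 and 15.22). The size of the late neutrophil median is therefore uncertain. Primary granule genes, made at the promyelocyte stage, did not stand apart (median -0.28 over 11 members, percentile 37.5); 1 of them, Gfi1, is also in the list of myeloid transcription factors. Elane had a log2 ratio of 0.17 and Prtn3 of -0.32, each by a single probe near the top of the scale on both arrays (15.24 and 15.07 for Elane, 14.79 and 15.11 for Prtn3), so their ratios are uncertain. Mpo, myeloperoxidase, was 3.42-fold higher by its brightest probe, which lay near the top of the scale at 15.29, and its other probes gave log2 ratios of 2.10 to 3.12. With several members this bright, the median of the primary granule list is uncertain as well. Nkg7 was 2.28-fold higher, Gfi1 2.36-fold lower, and Plac8 had a log2 ratio of -0.95. Myeloid transcription factors had a median of 0.75 (percentile 99.98), with 8 of 17 at least 2-fold higher and 2 lower; 4 of its members are in another list. Klf4, a monocyte factor, was 10.8-fold and Egr1 5.10-fold higher, Id1 2.82-fold lower. Red cell, lymphocyte and stromal markers, given below, were higher on the same array as these myeloid lists.

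Antigen presentation and dendritic cell genes had higher measured values in PirBTM in all 20 members above background on an array, 11 of them at least 2-fold by their bound, with a median of 1.63 (1.35 with bounds) above all random lists. H2-Eb1, a class II chain, was at least 283-fold higher and Cd74 219-fold by a probe near the top of the scale, whereas Cd80 and Zbtb46 lay near background on the PirBTM array and below it on the wild-type array. B2m is also a reference gene. PirB signalling and inhibitory receptor genes had a median of 0.91 (percentile 99.99), with 11 of 23 at least 2-fold higher and 2 lower, and 1 member in another list. Pira2, an activating paralogue of Pirb, was 8.42-fold higher and Lilrb4a at least 7.83-fold higher. Clec12a was 2.28-fold and Creb1 2.25-fold lower, although the second probe of Creb1 gave a log2 ratio of -0.26. Ptpn6, the phosphatase SHP-1, had a log2 ratio of 0.66, and Camk1 of -0.16. The Pira genes are near-identical to each other and to Pirb, and signal shared between their probes was not measured. These lists and the B cell and macrophage markers were higher on the same array.

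Genes of other marrow cell types were higher on the PirBTM array. Of 14 erythroid genes above background, all were higher, 13 at least 2-fold, and the median log2 ratio was 4.54, or 3.73 with bounds, above all random lists. All 14 were above background on the PirBTM array and 6 on the wild-type array. The lowest were Gata1 (at least 1.33-fold) and the globin gene Hbb-bt, whose brightest probe gave 2.80-fold at an intensity of 15.23 and whose other probes gave log2 ratios of 2.24 to 3.75; the globin genes are near-identical copies. B cell genes had a median of 3.53 (2.29 with bounds), above all random lists, with 8 of 11 at least 2-fold higher. Of these 11 members, 10 were above background on the PirBTM array and 2 on the wild-type array. The B cell call thus rests on members dark on the wild-type array, and too few were above background on both arrays for a percentile. Fcrla was at least 23.5-fold and Pou2af1, a B cell coactivator, at least 16.6-fold higher. Vpreb1 and Igll1, of the pre-B cell receptor, lay near background on both arrays. T and NK cell genes had a median of 2.81 (1.45 with bounds), above all random lists, with 7 of 11 at least 2-fold higher, among them Klrd1 (at least 7.57-fold) and Ccl5 (7.24-fold). Cd8b1 had a log2 ratio of -0.44, but 1.30 with the mean of its probes, and Prf1 of -0.05. The call for this list rests on members dark on the wild-type array, since its 3 members above background on both arrays lay at percentile 65.6.

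Megakaryocyte and platelet genes had a median of 1.80 (1.59 with bounds; percentile 99.99), with 9 of 12 at least 2-fold higher. Pf4, platelet factor 4, was 14.4-fold and Tubb1 at least 12.8-fold higher, while Itga2b had a log2 ratio of 0.63 and Clec1b lay near background. Its member Cd9 is also in the adhesion list. Stromal and endothelial genes had a median of 2.17 (0.92 with bounds), above all random lists, with 5 of 11 at least 2-fold higher, led by Cxcl12 and Bgn; Col4a1 had a log2 ratio of -0.56 and Cdh5 lay near background. This list lay at percentile 92.7 when only members above background on both arrays were used. Mast cell, basophil and eosinophil genes had a median of 1.88 (1.85 with bounds; percentile 99.71) over 7 members. Prss34, a basophil protease, and Epx, eosinophil peroxidase, were at least 7.53-fold and at least 6.98-fold higher, whereas Cpa3, the mast cell carboxypeptidase, was 3.43-fold lower and Prg2 had a log2 ratio of -0.13, which turned to 0.18 with cyclic loess. This list no longer stood apart at a detection limit of 0.05 or with members above background on both arrays.

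**Figure D2:**
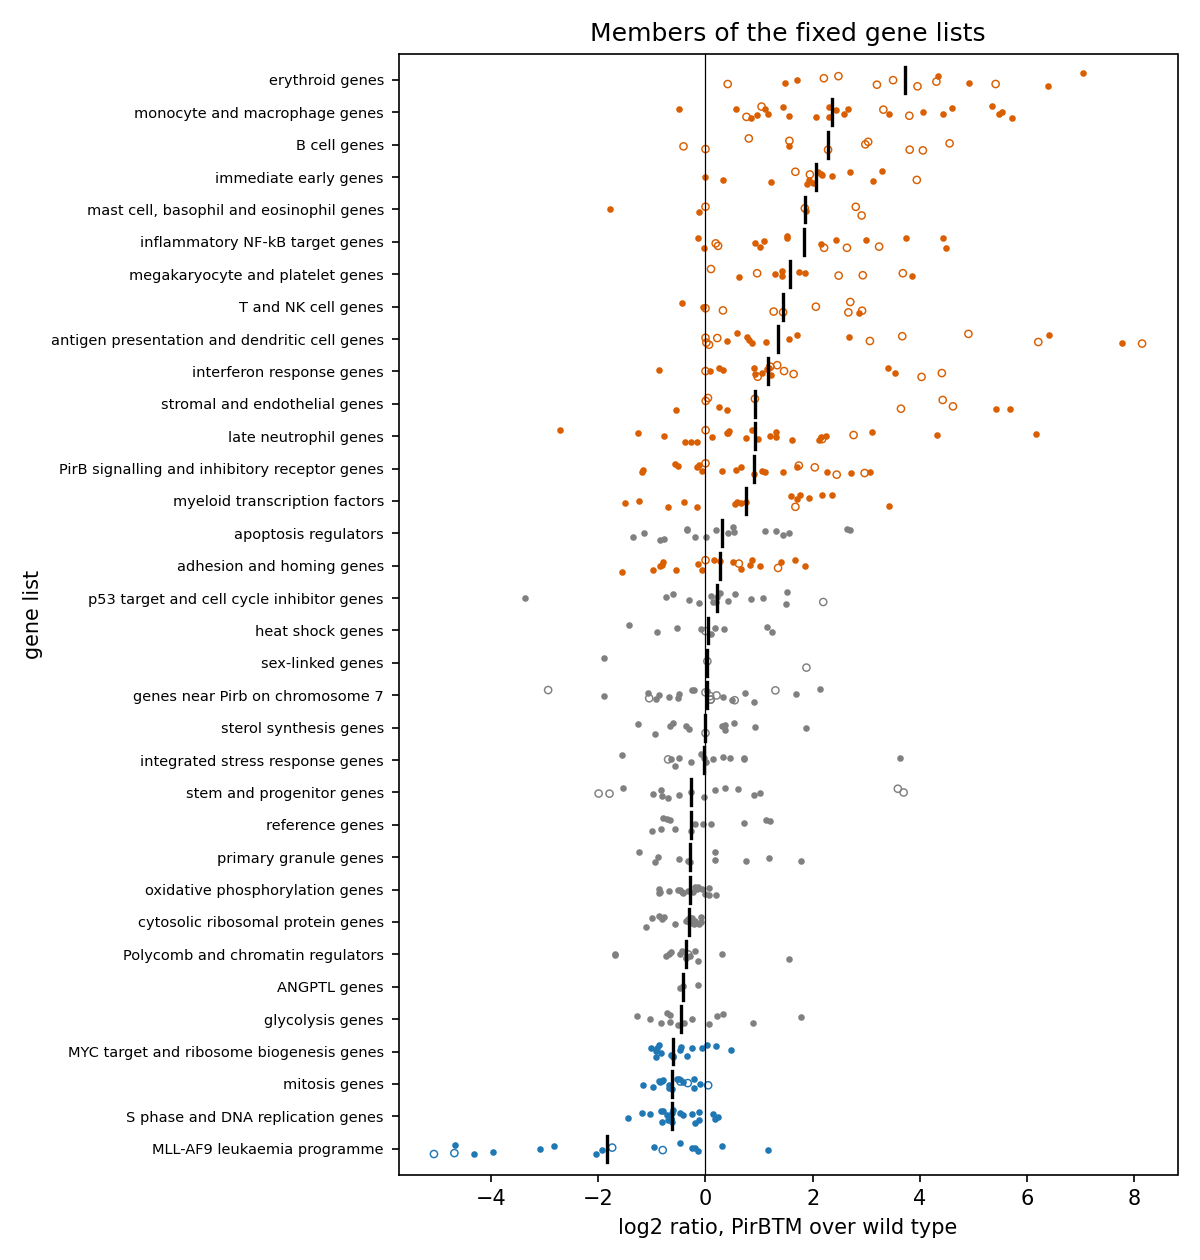
Log2 ratio (x axis, PirBTM over wild type) of each member of the 34 gene lists (y axis). Filled points were above background on both arrays, open points are bounds for members above background on 1 array, black bars mark list medians with bounds, and colour marks lists over the 99th percentile of random lists (orange), under the 1st (blue) or between (grey).

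Immediate early, NF-kB target and interferon response lists were also higher in PirBTM. Immediate early genes, genes induced within minutes of a stimulus, had a median of 2.16 (2.05 with bounds) above all random lists, with 14 of 16 at least 2-fold higher; 3 of them are in another list. Atf3 was at least 15.4-fold, Junb 9.86-fold and Fos 8.67-fold higher, whereas Ier2 and Ier3 had log2 ratios of -0.02 and 0.33. Inflammatory NF-kB target genes had a median of 1.85 (1.84 with bounds), above all random lists, with 13 of 18 at least 2-fold higher. Il1b was 22.3-fold and Nfkbiz 21.5-fold higher, while Cd44 (-0.15, also an adhesion gene) and Sod2 (-0.03) differed by less than the measuring error. Interferon response genes had a median of 1.20 (1.16 with bounds), above all random lists, with 12 of 20 at least 2-fold higher, led by Ifit3 (at least 21.2-fold) and Rsad2 (at least 16.3-fold); Bst2 had a log2 ratio of -0.87 and Mx1 lay near background. These lists were higher on the same array as the macrophage, lymphocyte and red cell markers.

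Proliferation genes were slightly lower in PirBTM, on the array with more signal from markers of other cell types. Relative to the median of all genes above background on at least 1 array (-0.15), the medians were -0.47 for S phase and -0.52 for mitosis, and both stayed below 0 in every alternative. S phase and DNA replication genes had a median of -0.63 (percentile 0.18), with 20 of 23 members lower and 3 of them at least 2-fold. Cdc45 was 2.72-fold and Tyms, thymidylate synthase, 2.27-fold lower, while Rrm2 (0.23) and Ccne1 (0.18) differed by less than the measuring error, and Rrm2 gave -0.21 with the mean of its probes. Mitosis genes had a median of -0.67 (-0.62 with bounds; percentile 0.11), with 18 of 19 lower and 1 at least 2-fold: Aurka, Aurora kinase A, was 2.25-fold lower, followed by Kif11 with a log2 ratio of -0.98. Cdc20 had a log2 ratio of -0.11, and Ube2c lay near background. MYC target and ribosome biogenesis genes had a median of -0.61 (percentile 0.74) over 17 members, of which Nop56 was 2.02-fold lower, Ppan had a log2 ratio of -0.93, Gnl3 of 0.47 and Polr1b of 0.19. The mitosis list lay at percentile 1.86 with the mean of all probes, and the MYC list stood apart in 2 of 9 alternatives.

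Adhesion and homing genes had a median of 0.52 (0.27 with bounds), at percentile 99.6, or 98.6 with bounds, and 2 of its members are in another list. Of 21 members, 5 were at least 2-fold higher, led by Cd9 (3.63-fold) and Itgb7 (3.17-fold), and Cd33 was 2.93-fold lower, followed by Cd63 with a log2 ratio of -0.98. This list did not stand apart without background correction or in the authors' deposited values.

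The other 13 lists did not stand apart. Apoptosis regulators had a median of 0.31 (percentile 98.5); Bcl2a1d and Bcl2a1b, near-identical prosurvival genes, were 6.51-fold and 6.25-fold higher, Bid was 2.56-fold lower, and Casp4 2.21-fold lower by 1 probe, while the other gave a log2 ratio of -0.09. The p53 target and cell cycle inhibitor genes had a median of 0.22 (percentile 94.1); Phlda3 was at least 4.58-fold and Trp53inp1 2.86-fold higher, Cdkn1c was 10.3-fold lower and Ei24 had a log2 ratio of -0.73. Medians were -0.46 for glycolysis genes (percentile 7.09), -0.28 for oxidative phosphorylation genes (33.5), -0.31 for cytosolic ribosomal protein genes (26.4; some near the top of the scale, such as Rps2 at 15.45 and 15.64) and 0.32 for sterol synthesis genes (91.7), the last 0 with bounds. They were 0.14 for heat shock genes (0.05 with bounds, percentile 79.3) and -0.44 for Polycomb and chromatin regulators (-0.36 with bounds, percentile 10.1). Integrated stress response genes had a median of -0.03 and a mean of 0.07, of opposite sign (percentile 73.6). The glycolysis list shares 2 members with other lists, and the ribosomal protein, p53 and integrated stress response lists 1 each. Within these, Pfkfb4 was 3.43-fold, Sqle 3.65-fold, Nupr1 12.4-fold and Cbx7 2.96-fold higher, and Pgam1 was 2.42-fold, Psat1 2.93-fold, Phf19 3.21-fold and Cbx8 3.21-fold lower. The 3 ANGPTL genes above background, which encode angiopoietin-like secreted proteins, had log2 ratios of -0.13 (Angptl7), -0.42 (Angptl6, the median, at percentile 33.2) and -0.47 (Angptl4), and Angptl7 was above 0 with median scaling and cyclic loess. Genes near Pirb on chromosome 7 had a median of 0.31 (0.03 with bounds; percentile 96.8) over 25 members, 1 of them in another list, with Lilra6 4.37-fold and Myadm 3.23-fold higher, and Isoc2a at least 7.65-fold and Nlrp12 3.72-fold lower. Reference genes, 4 of them in another list, had a median of -0.27 (percentile 36.9), between -0.99 for Rplp0 and 1.21 for Tfrc, the transferrin receptor. The sex-linked genes had a median of 0.12 over 3 members (0.04 with bounds, percentile 64.2). The X-inactivation transcript Xist was 3.70-fold lower and the Y-linked Eif2s3y at least 3.69-fold higher in PirBTM. The Y-linked Uty lay near background with a log2 ratio of 0.12, which is the list's median. Since the list mixes Xist with Y-linked genes, which a difference in sex would move opposite ways, its median cannot show such a difference.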

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

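The comparison in this part was chosen after the annotation was seen. Of 10396 probes that the annotation used here gave no single gene name, and which enter no comparison above, 1990 were above background on both arrays; they are listed because 148 of these, signals outside the main measurement, were at least 2-fold higher on the PirBTM array. Another 223 were at least 2-fold lower. The share at least 2-fold higher was below the 9.77% seen among named genes. The share at least 2-fold lower was above their 9.86%. The shares of unnamed probes count single probes and those of named genes count each gene by its brightest probe, so they are unlike measures. Log2 ratios ran from 7.63 for probe ILMN_1230194 to -7.34 for probe ILMN_1221149.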

How the results depend on the processing

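All alternatives were chosen in advance, and the range used to say that a list's median moved was set after the first values were seen. With 1 array per group, no replicate could be left out, and no paired analysis was possible because each group holds 1 sample. Of the 19 lists that stood apart, 13 stayed on their side of the percentile limits in every alternative that gave a value, and 1 list (apoptosis regulators) stood apart only with members above background on both arrays; B cell genes gave no value there, and nor did sex-linked genes, with under 3 such members. Of the named genes, 12 changed sign in some alternative, none with a log2 ratio beyond 0.44 either way in the main values, and so did 2 lists that did not stand apart (stem and progenitor genes and genes near Pirb). Of 154 named genes, 83 moved by more than the probe SD of 0.30 without background correction, 82 in the authors' deposited values, 62 with normexp and an offset of 50, 48 with the mean of probes, 10 with cyclic loess and 2 with median scaling. Without background correction the log2 ratio of Car1 was 5.38 in place of 7.05, that of Hoxa9 -3.68 in place of -4.68 (-3.44 with the mean of probes) and the measured one of Cd72 5.23 in place of 7.75, so the folds and bounds of the report hold for its own processing. Every list median below is relative to the median of the genes its members were drawn from in its setting, and the cause of each move was not tested unless named. At least 2-fold lower genes numbered 316 without background correction, 481 with normexp and an offset of 50, 403 with cyclic loess and 356 in the authors' deposited values, against 775. Without a detection filter 1560 genes were at least 2-fold higher, against 768, with 19057 genes counted in place of 7858. At 1.5-fold 1276 were higher and 2141 lower, and at 3-fold 427 and 188. Without background correction, which by construction leaves a constant in both arrays and shrinks ratios of dim genes, list medians were -1.02 (MLL-AF9 programme), 2.20 (monocyte and macrophage), 1.10 (antigen presentation), 2.60 (erythroid), 0.91 (megakaryocyte), 1.59 (B cell), 1.14 (T and NK cell), 1.09 (mast cell, basophil and eosinophil), 0.82 (stromal), 0.82 (interferon), 1.26 (NF-kB) and 1.89 (immediate early). In the authors' deposited values, which keep the background too, they were -1.04 (MLL-AF9 programme), 1.08 (antigen presentation), 2.69 (erythroid), 0.94 (megakaryocyte), 1.61 (B cell), 1.13 (T and NK cell), 1.10 (mast cell, basophil and eosinophil), 0.80 (stromal), 0.84 (interferon), 1.29 (NF-kB) and 0.28 (adhesion and homing). With normexp and an offset of 50 they were 1.31 (antigen presentation), 3.50 (erythroid), 1.26 (megakaryocyte), 2.42 (B cell), 1.89 (T and NK cell) and 1.38 (stromal). Without a detection filter, which adds members dark on both arrays, they were -1.18 (MLL-AF9 programme), 0.80 (late neutrophil), 2.42 (B cell), 0.60 (T and NK cell), 0.28 (mast cell, basophil and eosinophil), 0.52 (stromal) and 1.57 (NF-kB). With the mean of all probes they were -1.24 (MLL-AF9 programme), 3.54 (erythroid) and 2.76 (B cell). With members above background on both arrays only, they were -1.22 (MLL-AF9 programme), 0.18 (T and NK cell), 0.094 (mast cell, basophil and eosinophil), 0.63 (stromal) and -0.017 (genes near Pirb). Median scaling gave -0.49 for cytosolic ribosomal protein genes, and a detection limit of 0.05 gave 0.74 for mast cell, basophil and eosinophil genes. Background SDs of 14.0 and 11.7 limit the folds of dim genes.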

Other observations

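The tests by the lowest percentile over the settings, the SD of the programme's members, the programme's percentile and the Y-linked gene were chosen after the result was seen, although the settings themselves were chosen in advance. Second sets of markers were picked after the first lists had been seen and before the values of their own members were. Their medians were 2.67 for erythroid genes (1.62 with bounds), 3.12 for B cell genes (2.66), 1.63 for T and NK cell genes (0.48) and 1.14 for bone and endothelial genes (0.98). Of 12 further erythroid genes above background, 6 were at least 2-fold higher on the PirBTM array, among them Sptb, the red cell spectrin beta chain (at least 33.7-fold), and Trim10 (at least 21.5-fold). Of 13 further B cell genes, 10 were at least 2-fold higher, among them Mzb1 (at least 35.7-fold) and Ly6d (at least 14.4-fold), whereas Cd37 had a log2 ratio of -0.59. The members Cd72 and Fcmr of this set are also named in the report for their large bounds, and without them the median was 2.98 (2.14 with bounds). Rag1 and Dntt, of early lymphoid precursors, were not above background on either array. Of 8 T and NK cell genes, 3 were at least 2-fold higher, led by Il7r (5.81-fold) and Cd27 (5.12-fold), and 4 had a bound of 0. Of 10 bone and endothelial genes, 5 were at least 2-fold higher, led by Ebf3 (at least 8.57-fold) and Ibsp, bone sialoprotein (at least 3.69-fold). In all, 43 of 63 such markers were above background on the PirBTM array and 12 on the wild-type array. Of 44 markers of liver, brain and skeletal muscle, 6 and 7 were; Trf, transferrin, was 16.3-fold higher in PirBTM and the muscle gene Ckm at least 4.21-fold lower.

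Markers of red cells, B cells, T and NK cells, platelets and stroma were higher on the PirBTM array, with log2 intensities of 13.81 against 7.43 for Slc4a1 and 14.05 against 8.38 for Cxcl12, although the sample is labelled as leukaemic stem cells; how the cells were sorted is not given in the sources used here. Over the normalization and background settings the lowest percentile of these 5 lists was 99.89. This rank cannot decide whether processing was the cause, since each setting reworks the same 2 scanner columns and shifts the random lists alike. With members above background on both arrays only, the T and NK cell list lay at percentile 65.6 and the stromal list at 92.7. The B cell list had too few such members for a percentile. The direction did not depend on the normalization or background setting, since all 5 list medians stayed above the all-gene median. The size does depend on it: without background correction their medians, relative to that of genes above background on at least 1 array, were 2.60 in place of 4.69 (erythroid), 1.59 for 3.69 (B cell), 1.14 for 2.96 (T and NK cell), 0.91 for 1.95 (megakaryocyte) and 0.82 for 2.32 (stromal). Cells of other marrow types in the PirBTM sample are a candidate explanation. This is a hypothesis from 1 array, and no effect of the genotype was tested for this pattern. Of the second marker sets, 3 of 4 lay above the 99th percentile, and the fourth, bone and endothelial, at percentile 97.6 (99.8 with bounds). All 43 members that entered were above background on the PirBTM array, and the first lists of these cell types were already higher there. The sets thus repeat the pattern on further genes. They cannot tell such cells from expression by the leukaemic cells. Whether such cells were present stays open, as do their share of the RNA and any link to the genotype, the sort or the preparation.

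The MLL-AF9 programme was lower on the same array. Hoxa9 kept 3.91% of its wild-type intensity (up to 9.20% over the normalizations, background settings and probe rules), Meis1 5.03% (up to 8.64%) and Hoxa7 6.38% (up to 12.7%), whereas Myb kept 24.4% (23.1% to 44.2%) and Mef2c 26.1% (up to 37.3%). Pbx3 kept 11.8% (up to 29.6%) and Cdk6 14.1% (up to 28.7%), between these members. Without background correction both kept about as much as Mef2c (28.7%). Fewer leukaemic cells in the PirBTM sample are a possible explanation of the lower programme. They would lower leukaemia-specific genes by a like amount and genes that normal progenitors also express by less. Which members are of either kind was not measured here. Over 7 members at least 2-fold lower and above background on both arrays, the SD of the log2 ratio was 1.09. The measuring SD was 0.30. These members were chosen for being lower, and dim members can fall less far before they reach background. No member is known to lack a source outside the leukaemic cells either, so an uneven fall does not decide. A lower programme within leukaemic cells of the mutant cannot be told apart from fewer such cells here. The list lay at percentile 0 of random lists, as both would give, and markers of other cell types are not level between the arrays.

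Xist was 3.70-fold lower and Eif2s3y at least 3.69-fold higher on the PirBTM array, and all 4 Xist probes above background gave log2 ratios between -2.03 and -1.55. A different sex makeup of the 2 samples (of donors, or of donor and host cells) is a possible explanation. The other Y-linked gene above background on an array, Uty, had a log2 ratio of 0.12. Its intensity was close to background on both arrays, so it cannot decide. Kdm5d, also Y-linked, was above background on neither array (log2 intensity 5.22 on the PirBTM array and 4.55 on the wild-type array). The explanation stays open, since it rests on Eif2s3y alone among Y-linked genes, and Xist was well above background on both arrays. No effect of the genotype was tested for this pattern.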
